A study of Mus musculus with 4 samples.

How the data were processed

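RNA sequencing libraries had been made from thymus of C57BL/6J mice, 1 library for each of 4 groups: wild type and Camk2g knockout, each with and without N-methyl-N-nitrosourea (MNU). The libraries were prepared from total RNA with a TruSeq kit and all RNA had an integrity number above 7.5, per the labels' protocols. TopHat2 2.0.8b, edgeR and the mouse build mm9 are named, without role or order, per the submitters' processing notes. The gene counting tool, the annotation and the gene filter are not given in the sources used here.

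The deposited table held a signal for each gene and library, named normalised counts per the file headers, for 10598 gene symbols. The values were not whole numbers, were never negative, and summed to between 32911362 and 34836257 per library. Low values lay near steps of 0.991, 0.929, 1.06 and 1.02 units in wild type without MNU, wild type with MNU, knockout without MNU and knockout with MNU, so that 1 unit stood for about 1 read. The method of normalisation is not given in the sources used here. Because the deposited values were no longer whole reads, no count model was applied to them and counting intervals were not computed. The normalisation could have moved low values by an offset, and a value of 0 was therefore reported as listed at 0, with no fold difference against it.

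Groups were taken from the labels. The values were used as scaled by the authors, 10 was added as a pseudocount and the log2 was taken, and genes with a mean of at least 10 over the 4 libraries were kept, which removed 11 genes and left 10587. With 1 library per group there was no replicate spread, so no p-value was computed for any gene and an additive model was not fitted, since its residual would be the genotype-by-MNU difference itself. Genes were counted as higher or lower at a difference of at least 2-fold on the log2(value + 10) scale, which understates the difference of low genes, and the difference of the MNU changes between genotypes was counted at 2 or more on the log2 scale. Fold differences printed for single genes are ratios of the normalised counts themselves.

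For 36 gene lists the median log2 difference of the measured members was computed. Its percentile was taken among 10000 random lists of the same size matched on mean expression in 20 bins, and a list was said to stand apart under percentile 1 or over percentile 99. The percentiles describe these libraries and not the conditions. Percentiles were given to the 32 lists with at least 5 measured members, and 2 lists had no member among the genes analysed here. Intervals for list medians are 95% bootstrap intervals over the members (2000 draws) and describe the spread of the genes, not of animals. The lists, comparisons, thresholds and the rule for naming genes were fixed before the data were examined. That rule named Camk2g, Myc and their family members and the sex-linked genes, the 8 genes with the largest increase and the 8 with the largest decrease in each comparison whose higher library reached 100, leaving out provisional symbols, and up to 4 members of each list with the largest difference. Genes outside it are said to be so where they appear, and some genes within it are not reported here.

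Of the symbols, 10521 matched a RefSeq gene table, and 14 had the form of calendar dates, as spreadsheet software makes of some symbols. No coordinates are given, since the reference annotation at hand was of another build than mm9. Genes with near-identical copies (Ccl21a, Ccl21b and Ccl21c; Hba-a1 and Hba-a2; Hbb-b1 and Hbb-b2; the Mup cluster; Xlr3a and Xlr3c; Il22 and Iltifb; histone genes) are uncertain individually, since reads can be split or shared between the copies.

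The alternatives tried were a pseudocount 4 times smaller and 4 times larger, no filter and a filter 10 times as high, and median-of-ratios and upper-quartile scaling. Others were a 4-fold threshold (3 on the log2 scale for the difference of MNU changes) and unmatched random lists. The last left out haemoglobin, immunoglobulin, mitochondrial and the 50 most abundant genes. It removed no mitochondrially encoded gene, since none was among the genes analysed here, and Igj was its only immunoglobulin-related gene. After the data were examined, a share of the wild-type MNU profile was estimated in the knockout library without MNU. It was taken as the median over 42 genes with more than 1000 units in wild type with MNU and more than 20-fold higher there than in both wild type without MNU and knockout with MNU, each gene's level being set against the mean of those 2 libraries, and 72 genes between 6-fold and 20-fold higher were held out. Alternatives with this share subtracted, or with that library left out, were added. On simulated values for the comparison of MNU in wild type over 10518 genes, the 2-fold rule recovered 100% of 200 genes changed 3-fold and 100% of those changed 8-fold, with 0 other genes called, and 2.0% of unchanged lists stood apart. A simulated share of 15% was recovered as 15.0%, on a library built from the same 2-library mean that the estimate uses. The simulated values carried counting noise alone. They therefore say nothing of differences between animals or of genes that vary together. In the data, 18 to 23 of the 32 lists stood apart in each comparison. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.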

Results

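Thymus transcriptomes were compared between wild-type mice and mice lacking Camk2g, which encodes the gamma subunit of calcium/calmodulin-dependent protein kinase II, with and without MNU, an alkylating mutagen used to induce T-cell lymphoma in mice. MNU had been given as a single injection of 75 mg/kg at 4 to 5 weeks of age, and the labels give a treatment time of 6 months. The design asked how loss of Camk2g alters gene expression in the thymus under malignant and normal conditions. Each of the 4 groups was represented by 1 library, with normalised counts summing to 33288000 in wild type without MNU, 34836257 in wild type with MNU, 32911362 in knockout without MNU and 33230818 in knockout with MNU. None of the differences below has a replicate check.

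Camk2g stood at 2749 normalised counts in wild type without MNU and 3173 in wild type with MNU. It stood at 489 in knockout without MNU, 17.8% of the wild-type level without MNU, and at 29.7 in knockout with MNU, 1.08% of that level. Both knockout libraries were thus below both wild-type libraries, and the one without MNU held 16.5-fold more Camk2g than the one with MNU. Myc, named in the title of the study for the stability of its protein, differed little at the RNA level, at 2654, 3303, 2574 and 2736 in wild type without MNU, wild type with MNU, knockout without MNU and knockout with MNU. The paralogs Camk2a (1153, 1726, 1231 and 1202 in the same order) and Camk2d (1800, 1594, 1787 and 2055) stayed within 2-fold. Xist, transcribed from the inactive X chromosome, was abundant in all 4 libraries (77487, 64411, 78388 and 71273 in the same order), the pattern of female tissue. Mycn, Mycl, Camk2b and the Y-linked genes were not analysed here.

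**Figure D1:**
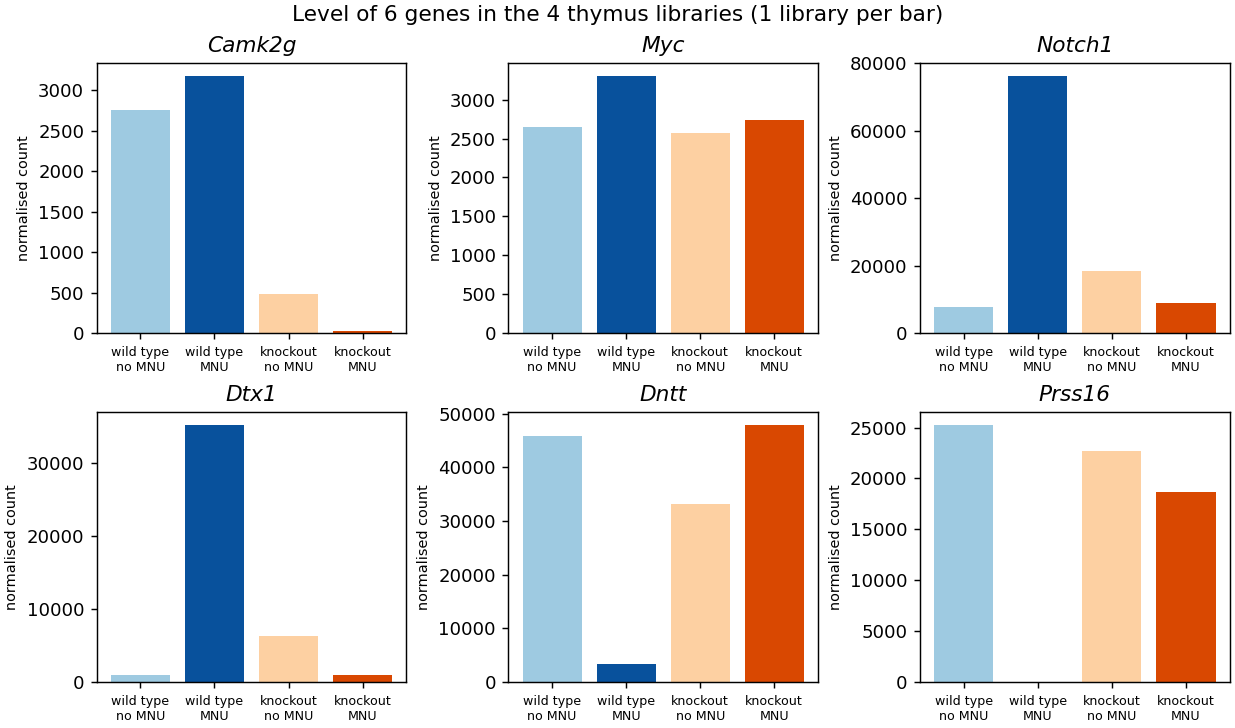
Normalised counts of Camk2g, Myc, Notch1, Dtx1, Dntt and Prss16, with 1 bar for each of the 4 libraries and each vertical axis starting at 0. Notch1 reached 76273 and Dtx1 35307 in wild type with MNU, where Prss16 stood at 8.26, while Camk2g stood at 489 and 29.7 in the knockout libraries.

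Wild type with MNU stood apart from the other libraries as a whole. Across genes, which are not independent replicates, Spearman's rho was 0.845 between the wild-type libraries, against 0.981 between the knockout libraries and 0.982 between the libraries without MNU. Knockout with MNU and wild type without MNU had a rho of 0.981, and 283 of 10587 genes differed at least 2-fold between them.

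A measured feature of the knockout library without MNU bears on each comparison that uses it. The 42 genes more than 20-fold higher in wild type with MNU than in both wild type without MNU and knockout with MNU were all higher in knockout without MNU than in those 2 libraries, at a median share of 15.4% of the wild-type MNU level (5th to 95th percentile 13.9% to 18.5%). Among the 42, Gm14475, Gm14476, Gm14477 and Gm14479, outside the naming rule, had identical values in every library (share 18.5%). They are not separate measurements and lie at the upper end of that range. For the 72 genes that were 6-fold to 20-fold higher the median share was 16.2% (5th to 95th percentile 12.5% to 22.3%, lowest 10.6% and highest 34.8%). For Camk2g, above its level in knockout with MNU, the share was 14.6%.

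**Figure D2:**
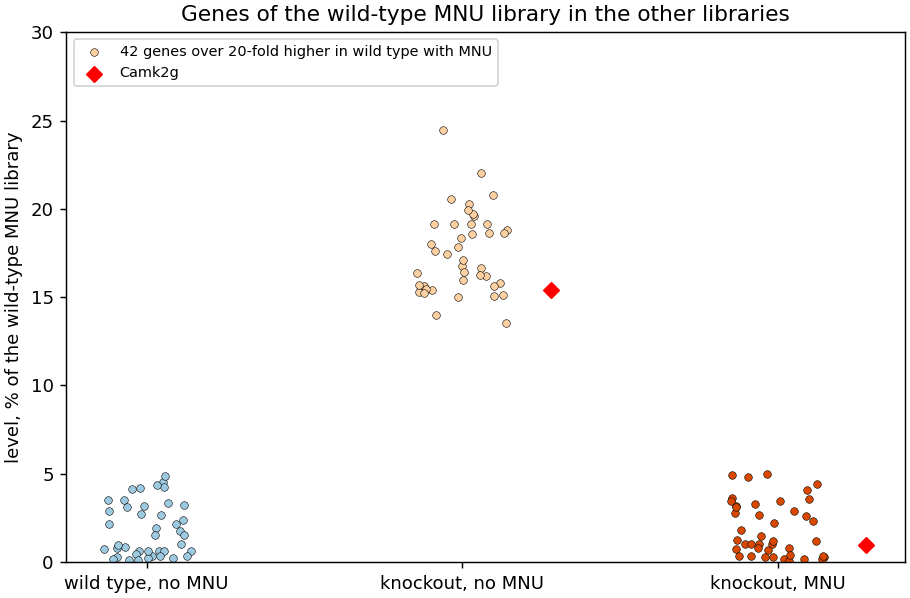
Level of the 42 genes more than 20-fold higher in wild type with MNU (circles) and of Camk2g (diamonds, knockout libraries) as a percentage of their level in wild type with MNU, with no baseline subtracted. The medians over the 42 genes were 1.53% in wild type without MNU, 17.3% in knockout without MNU and 1.22% in knockout with MNU, and Camk2g stood at 15.4% and 0.93% in the knockout libraries.

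In wild-type mice, the thymus with MNU held almost no transcripts of the epithelial framework and few of B cells, NK cells and dendritic cells, while NOTCH pathway and cell-cycle transcripts were higher. Notch1, the receptor that commits progenitors to the T lineage, was 9.64-fold higher (7913 against 76273), Notch3 was 7.45-fold higher and Dtx1, a NOTCH-induced ubiquitin ligase, was 37.9-fold higher. Prss16, the thymus-specific serine protease of cortical epithelium, stood at 25293 without and 8.26 with MNU. At the 2-fold rule 756 of 10587 genes were higher and 1500 were lower with MNU.

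Among T-lineage genes, 8 of 12 measured NOTCH target genes were at least 2-fold higher and 3 lower, with a median log2 difference of 1.91 (interval -0.25 to 2.94). Heyl was 8.14-fold higher, whereas Hey1 was 10.3-fold lower. Of 31 double-positive thymocyte genes 11 were lower and 4 higher (median -0.78). Dntt, the polymerase that adds nucleotides at receptor gene joins, was 13.6-fold lower, the homing receptor Ccr9 6.03-fold lower and Cd5 4.80-fold lower, and Ptcra, the pre-T-cell receptor chain, was 4.11-fold higher. T cell identity genes had a median of -0.49, with Cd28 2.74-fold lower and Zap70 2.26-fold higher. Mature single-positive T cell genes had a median of -1.56 (17 of 29 lower), and immediate-early and stress genes, among them Egr1 (5.49-fold lower) and Egr2 (10.2-fold lower), a median of -1.29 (12 of 21 lower). Of the early thymocyte genes 3 of 11 were higher and 3 lower, with Il7r 14.7-fold lower. Among T lymphoma genes, Ccnd2 was 14.5-fold lower, Bcl2 was 8.12-fold lower and Cdkn2a stood at 34.7 without and 347 with MNU, and that list did not stand apart (median -0.19).

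Growth and division genes were higher together by less than 2-fold. The median log2 differences were 0.74 for S phase genes (7 of 36 at least 2-fold higher), 0.66 for G2/M genes (3 of 36), 0.60 for MYC-activated nucleolar and growth genes (4 of 47 higher and 1 lower) and 0.56 for cytosolic ribosomal protein genes (1 of 43), all above percentile 99. Mcm5, a subunit of the replicative helicase, was 2.25-fold higher, Bub1b, a spindle checkpoint kinase, 2.31-fold higher, Odc1, the first enzyme of polyamine synthesis and a MYC target, 3.38-fold higher, and Bysl 3.13-fold lower. Mki67, a proliferation marker, stood at 26753 without and 53226 with MNU. Alkylation and mismatch repair genes had a median of 0.45, with Mpg 2.04-fold higher. The MYC protein turnover genes (median 0.17, 0 of 24 beyond 2-fold), the CaMK and calcium signalling genes (-0.14), the MYC family (-0.30), p53 targets (-0.13), glycolysis genes (0.35), oxidative phosphorylation genes (0.17) and replication-dependent histone genes (0.08) did not stand apart. Within those lists, Pkm2, a glycolytic enzyme, was 2.45-fold higher and Perp, a p53 target, was 24.1-fold lower.

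Markers of other cell types differed in size and direction. Thymic epithelial genes had a median log2 difference of -6.13 (interval -7.90 to -4.35), with 20 of 22 at least 2-fold lower. Among them Krt5, a basal keratin, stood at 10373 without and 7.33 with MNU, Tbata at 12926 and 8.26, and Krt17 at 5838 and 4.54. Dendritic cell and MHC class II genes followed at -3.70 (14 of 16 lower), with Cd74, the invariant chain, 37.9-fold lower and H2-Eb1 33.3-fold lower. NK and cytotoxic genes stood at -3.21, B cell genes at -2.78 (12 of 15 lower), interferon-induced genes at -2.38 (25 of 30 lower, Cxcl10 29.5-fold) and plasma cell genes at -1.76. Adipocyte genes had a median of -3.31 (25 of 27 lower), and Lep, the adipocyte hormone leptin, stood at 2877 without MNU and was listed at 0 with it. Lymph node stroma and parathyroid genes had a median of -2.79, where the chemokine Ccl21b was 210-fold lower and Cxcl13 was 18.6-fold higher. By contrast, neutrophil genes (median 1.40, 6 of 8 higher, Ngp 7.31-fold) and macrophage genes (0.60, 8 of 23 higher and 3 lower) were higher, among the latter the scavenger receptor Marco (26.2-fold) and the haem oxygenase Hmox1 (9.71-fold). Fibroblast genes did not stand apart, with 9 of 24 higher, 4 lower, a median of -0.20 and a mean of 0.24, and included Pdgfrb (6.27-fold higher) and Gsn (6.53-fold lower). Endothelial genes (-0.39) and erythroid genes (-0.74) did not stand apart either. Of the 4 measured muscle genes, Tnnt1 was 16.8-fold higher, Mylpf 2.32-fold lower, and Des and Acta1 were within 2-fold.

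The largest increases outside these lists were of genes with little or no signal in the thymus without MNU. The transcription factor gene Sall3 stood at 2.96 without and 3434 with MNU, the presynaptic gene Erc2 at 4.95 and 3023, the cytokine Il22 at 3.95 and 1624 with its near-identical copy Iltifb at 1.97 and 1954, the protease gene Cym at 7.92 and 2612, Sh3gl3 at 28.7 and 4791, Rpl3l at 5.94 and 1893, and the potassium channel gene Kcnf1 at 5.94 and 1660. Other large decreases were of Fcgbp (13996 against 12.9), the epithelial transcription factor Pax1 (4497 against 2.68) and Crip3 (3382 against 0.82).

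In knockout mice, the thymus with MNU had dendritic, thymocyte and T cell identity transcripts near their levels without MNU. Adipocyte genes were lower, as were NOTCH target genes in the values as deposited. Stromal and thymic epithelial genes were lower by less than 2-fold in the median, and neutrophil genes were higher in the median. Prss16 stood at 22697 without and 18685 with MNU, and Cd74 at 64788 and 73844. At the 2-fold rule 35 genes were higher and 312 lower with MNU. The 8 largest decreases were of Sall3, Dpf1, Sh3gl3, Cym, Erc2, Iltifb, Kcnf1 and Il22, all of them high in wild type with MNU, and the size of these decreases rested on the knockout library without MNU: Sall3 stood at 480 there, at 1.05 in knockout with MNU and at 2.96 in wild type without MNU. With the wild-type MNU share subtracted the differences of Sall3, Dpf1, Erc2, Iltifb and Kcnf1 turned positive. Those of Cym and Il22 were then within 2-fold, and Sh3gl3 stayed lower with a log2 difference of -1.21. All of these genes were among those that set the share. Levels that the subtraction made negative were raised to the lowest value allowed. The positive signs therefore follow from the construction of the subtraction and are no separate check on the share. With that share subtracted 198 genes were lower, of which 156 were among the 312, and with wild type without MNU in place of that library 166 genes were higher and 117 lower in knockout with MNU.

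Adipocyte genes had the lowest median in the knockout with MNU, at -1.22 (interval -1.52 to -0.98), and 18 of 27 were at least 2-fold lower. The lipid droplet genes Plin4 and Cidec were 4.04-fold and 3.65-fold lower, the adipokine genes Cfd and Retn 3.87-fold and 3.90-fold lower, and Ucp1, the uncoupling protein of brown fat, stood at 1224 and 1256. The adipocyte median was -1.45 with the share subtracted and -1.15 against wild type without MNU. Fibroblast genes had a median of -0.59 (5 of 24 lower, Fn1 2.19-fold), and with the share subtracted one of -0.46 with 0 of 24 lower. Endothelial genes had a median of -0.32 and thymic epithelial genes one of -0.34 with 0 of 22 beyond 2-fold, both under percentile 1, and with the share subtracted the thymic epithelial median was -0.57 with 1 of 22 lower.

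Neutrophil genes were higher in the median in the knockout with MNU, as they were in wild type with MNU. Ngp was 5.56-fold, Camp 5.29-fold, S100a8 3.81-fold and S100a9 3.40-fold higher. The list had a median of 1.34 (interval -0.12 to 2.04), with 4 of 8 genes at least 2-fold higher and the others within 2-fold. Erythroid genes had a median of 1.05, with Hbb-b1 2.27-fold higher, but against wild type without MNU, in place of the knockout library without MNU, the erythroid median was -0.44. B cell genes had a median of 0.76, with 1 of 15 beyond 2-fold (Faim3, log2 difference 1.21), and with the share subtracted one of 0.56 with 0 of 15. Lymph node stroma and parathyroid genes had a median of 0.62. The parathyroid hormone gene Pth stood at 2.22 without and 804 with MNU, the lymph node endothelial mucin gene Glycam1 at 6.47 and 530, the neuroendocrine granule gene Chga at 45.8 and 1262, the airway epithelial gene Bpifa1 at 80.8 and 3141, Eps8l1 at 344 and 1571, and the X-linked Xlr3a and Xlr3c at 57.5 and 376 and at 104 and 467. NOTCH target genes had a median of -0.60 (4 of 12 lower) with Dtx1 6.45-fold and Notch1 2.05-fold lower. With the share subtracted that median was -0.01 and no longer stood apart, but against wild type without MNU it was -0.26, under percentile 1. S phase (-0.08), G2/M (-0.11) and MYC-activated genes (-0.07) also had medians under percentile 1. With the share subtracted these were 0.12, 0.041 and 0.054, where the matched random medians were 0.054, 0.057 and 0.051. S phase genes then stood above percentile 99, and G2/M and MYC-activated genes no longer stood apart. Against wild type without MNU the S phase (-0.084) and G2/M medians (-0.085) stayed under percentile 1. Double-positive thymocyte (0.25), T cell identity (0.22), mature single-positive (0.28), macrophage (0.23), dendritic (0.20) and histone genes (0.31) had small positive medians above percentile 99 with at most 1 member beyond 2-fold in any of these lists. Plasma cell (0.21), T lymphoma (0.14) and interferon-induced genes (0.11) also lay above percentile 99, and ribosomal protein (-0.12) and oxidative phosphorylation genes (-0.09) under percentile 1. With the share subtracted the interferon-induced median turned to -0.07, and the mature single-positive (0.097), dendritic (0.016) and plasma cell medians (0.094) no longer stood apart. Against wild type without MNU the double-positive thymocyte median turned to -0.21, the T lymphoma median to -0.02 and the ribosomal protein median to 0.056, and the T cell identity (0.032) and MYC-activated medians (-0.01) no longer stood apart.

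**Figure D3:**
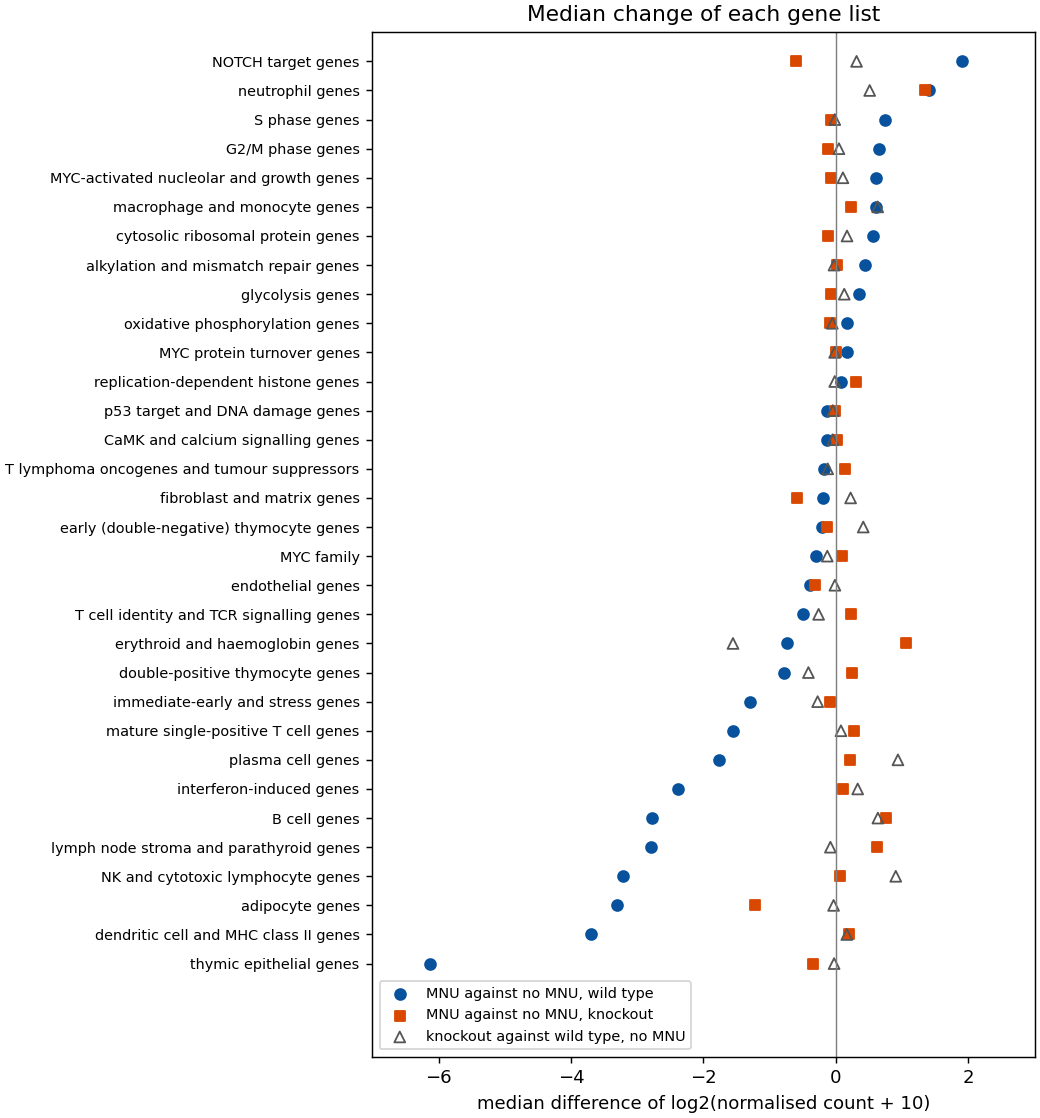
Median difference of log2(normalised count + 10) for each of the 32 gene lists with at least 5 measured members, for MNU against no MNU in wild type (circles) and in knockout (squares), and for knockout against wild type without MNU (triangles). Thymic epithelial genes lay at -6.13 in wild type and -0.34 in knockout, and NOTCH target genes at 1.91 and -0.60.

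Without MNU, the knockout thymus held more transcripts of plasma cells, NK cells, B cells and macrophages and fewer of red cells and double-positive thymocytes than the wild-type thymus. Igj, the joining chain of secreted antibody, stood at 8896 in wild type and 20492 in knockout, and Klrk1, an activating NK receptor, was 3.21-fold higher. At the 2-fold rule 274 genes were higher and 38 lower in the knockout, and with the wild-type MNU share subtracted 182 were higher, 132 of them among the 274, and 53 lower. With knockout with MNU in place of the knockout library without MNU, 166 genes were higher and 117 lower than in wild type without MNU.

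Plasma cell genes had a median log2 difference of 0.94 (3 of 9 at least 2-fold higher, Derl3 3.34-fold), NK and cytotoxic genes 0.90 (4 of 12, Klrb1c 2.90-fold and Nkg7 2.25-fold), B cell genes 0.63 (2 of 15, Blk 2.19-fold and Cd72 2.08-fold) and macrophage genes 0.63 (4 of 23, Marco 5.93-fold and Hmox1 2.58-fold, both high in wild type with MNU). With the share subtracted 0 of 23 macrophage genes were at least 2-fold higher, at a median of 0.65, and 7 of 12 NK and cytotoxic genes were. Interferon-induced genes (0.33) and early thymocyte genes (0.41) also stood above percentile 99. Haemoglobin genes were lower, Hba-a1 2.94-fold and Hbb-b1 2.98-fold, and the erythroid median was -1.55 with 5 of 6 genes lower. Double-positive thymocyte genes had a median of -0.42 with 0 of 31 beyond 2-fold, and Rag1, a recombinase of receptor gene assembly, stood at 123683 in wild type and 73746 in knockout. Immediate-early genes had a median of -0.28, with Nr4a1, a gene induced by T-cell receptor signals, 2.35-fold lower. The NOTCH target median of 0.31 turned to -0.08 with the share subtracted, where the matched random median was -0.033, and no longer stood apart. The remaining lists that stood apart had medians between -0.26 (T cell identity genes) and 0.22 (fibroblast genes). With the share subtracted the G2/M median turned to -0.12, under percentile 1, where the matched random median was -0.064. The MYC-activated (-0.03, random median -0.047), glycolysis and T lymphoma medians no longer stood apart. S phase (-0.20), histone (-0.19), mature single-positive (0.28), thymic epithelial (0.17) and adipocyte genes (0.10) then stood apart, which they had not done before.

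Among the largest increases were the genes of the major urinary proteins, lipocalins made mainly by liver. The median of 14 Mup genes was 13.4 in wild type without MNU, 15.2 in wild type with MNU, 392 in knockout without MNU and 114 in knockout with MNU, and all 14 were at least 2-fold higher in both knockout libraries than in wild type without MNU. Mup2 stood at 47.6 in wild type and 1465 in knockout without MNU, and Mup10, Mup15 and Mup16 were among the same top genes. The other top increases were Sall3, Erc2, Iltifb and Cym, genes of the wild-type MNU library. Pth (257 against 2.22) and Chga (337 against 45.8) were the largest decreases, followed by Camk2g (5.63-fold lower), Cdk5rap1 (4.31-fold), Fabp3 (4.08-fold), Eps8l1 (3.86-fold), Npr3 (3.43-fold) and Akr1cl (3.21-fold). These values are without the wild-type MNU share subtracted. Camk2g held a share of 14.6% in this library, so subtraction lowers it further.

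With MNU, epithelial, dendritic, lymphoid and interferon-induced transcripts were higher in the knockout thymus than in the wild-type thymus. NOTCH and cell-cycle transcripts were lower. With 1 library per group, an effect of genotype cannot be told apart from a difference between single thymus samples. Such a difference could lie in tumour content, which was not assessed here. Prss16 stood at 8.26 in wild type and 18685 in knockout, Dtx1 was 36.1-fold lower and Notch1 8.49-fold lower in the knockout. At the 2-fold rule 1586 genes were higher and 780 lower in the knockout. Camk2g was 107-fold lower and Myc was 1.21-fold lower.

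Thymic epithelial genes had a median log2 difference of 6.02 (interval 4.04 to 7.47), with 20 of 22 higher. NK and cytotoxic genes followed at 4.02, dendritic cell and MHC class II genes at 3.98 (16 of 16 higher), B cell genes at 3.88 (13 of 15, Ms4a1 log2 difference 5.97), interferon-induced genes at 2.95 (28 of 30, Oas3 14.1-fold), plasma cell genes at 2.80, adipocyte genes at 1.75 (20 of 27) and mature single-positive T cell genes at 1.66 (22 of 29). Of the last, Ccr7, which guides mature thymocytes to the medulla, was 76.0-fold higher, and Cd69 stood at 41.7 in wild type and 1751 in knockout. Dntt was 14.2-fold higher, Il7r 22.3-fold and Ccnd2 19.8-fold. The NOTCH target median was -2.15 (interval -3.17 to 0.21), with 8 of 12 at least 2-fold lower and 3 higher. Heyl and Notch3 were 10.7-fold and 9.55-fold lower. S phase genes had a median of -0.85 (12 of 36 lower, Mcm5 2.32-fold), G2/M genes -0.73 (7 of 36 lower, Cdc25c 3.17-fold), MYC-activated genes -0.57 (4 of 47 lower, Odc1 3.56-fold) and ribosomal protein genes -0.51. Immediate-early genes (1.09), double-positive thymocyte genes (0.54), T cell identity genes (0.51), lymph node stroma and parathyroid genes (3.77) and alkylation and mismatch repair genes (-0.51) also stood apart. The MYC protein turnover genes (-0.25) did not stand apart, with 0 of 24 beyond 2-fold.

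In the comparison of the MNU change between genotypes, the thymic epithelial, dendritic and lymphoid genes differed towards loss in wild type. NOTCH and cell-cycle genes differed towards gain. Here too, genotype cannot be told apart from a difference between single thymus samples. The difference of the MNU changes was at least 2 on the log2 scale for 385 genes higher and 701 lower in wild type than in knockout, 1086 of 10587. With the wild-type MNU share subtracted the total was 936. The list medians were -5.94 for thymic epithelial genes, -4.11 for dendritic genes and -3.71 for B cell genes. They were 2.51 for NOTCH target genes (interval -0.52 to 4.26), 0.83 for S phase genes and 0.69 for MYC-activated genes. Dtx1 differed by 7.91 and Camk2g by 3.86. Both values rest in part on the knockout library without MNU. Dtx1 stood at 6307 there and 978 in knockout with MNU, and Camk2g, the deleted gene, held a share of 14.6% there.

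The genes at least 2-fold changed the same way in both genotypes numbered 90, of which 9 were higher and 81 lower, where independent lists would share 2.5 and 44.2. Another 198 genes went opposite ways: 182 were higher with MNU in wild type and lower in knockout, where independent lists would give 22.3, and 16 the reverse, where they would give 5.0. Of the 182, 179 were also higher, by any amount, in knockout than in wild type without MNU, and 29 remained with the wild-type MNU share subtracted. With that share subtracted 136 genes changed the same way and 38 opposite ways.

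**Figure D4:**
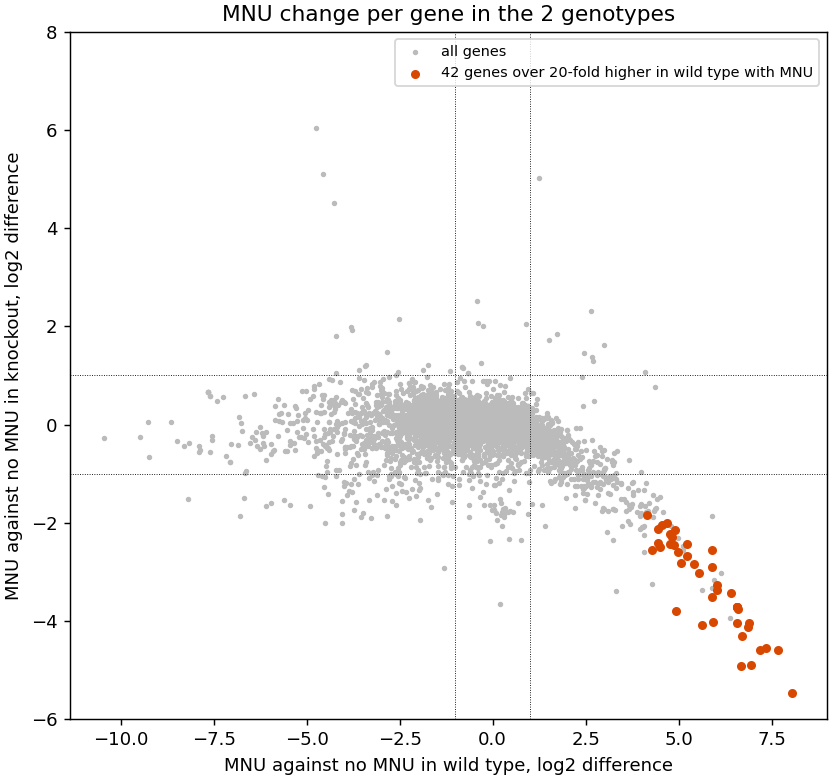
MNU change of each gene in wild type (horizontal axis) and in knockout (vertical axis) as differences of log2(normalised count + 10), with dotted lines at the 2-fold threshold. The 42 genes more than 20-fold higher in wild type with MNU are orange and all lie at positive values in wild type and negative values in knockout, Sall3 being the farthest at 8.05 and -5.47.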

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

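The tests weighed below were chosen after the results they concern were seen, and the thresholds for reading them were set at that point. The differences between genotypes were not tested, since each group had 1 library, and a check for outlying samples within a group was not possible for the same reason.

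The MNU change went opposite ways in the genotypes, by at least 2-fold in each, for 198 genes. The difference of the MNU changes, wild type minus knockout on the log2 scale, was 13.52 for Sall3, 12.26 for Erc2, 11.91 for Iltifb, 11.86 for Sh3gl3, 11.80 for Cym, 11.58 for Dpf1, 11.01 for Kcnf1, 10.99 for Il22 and 10.94 for Rpl3l. It was -10.80 for Pth, -9.68 for Bpifa1, -8.76 for Chga and -4.68 for Eps8l1. Lists whose medians stood apart in opposite directions in the genotypes differed by 2.51 for NOTCH target genes (interval -0.52 to 4.26). The differences were 0.83 for S phase, 0.81 for G2/M, 0.69 for MYC-activated and 0.66 for ribosomal protein genes. The differences were -0.91 for double-positive thymocyte, -0.77 for T cell identity, -1.54 for mature single-positive T cell, -3.71 for B cell, -2.19 for plasma cell, -4.11 for dendritic cell, -2.43 for interferon-induced and -3.77 for lymph node stroma and parathyroid genes. With the wild-type MNU share subtracted 38 genes went opposite ways, and the NOTCH target, S phase, G2/M, MYC-activated, mature single-positive, plasma cell, dendritic cell and interferon-induced lists no longer stood apart in opposite directions.

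The knockout library without MNU held the genes of the wild-type MNU library at a low share. A lymphoma of the knockout thymus itself would bring no Camk2g if the deletion was complete, yet the share of Camk2g, 14.6%, lay within the 13.9% to 18.5% range of the 42 genes, and a label swap with a wild-type library is argued against by Camk2g at 17.8% of the lower wild-type library. Part of the wild-type MNU sample in the knockout library without MNU is a candidate explanation. The 72 genes not used to estimate the share had a median of 16.2%, with a wider spread than the 42 (5th to 95th percentile 12.5% to 22.3%). Subtraction, which by construction removes about that much, took those at least 2-fold higher than in wild type without MNU from 51 to 5. A tumour in that thymus would give these values too only if it held these genes in nearly the same proportions. Whether one could was not tested, so these values alone do not tell the 2 explanations apart. Whether a mixture arose in tissue, RNA, library or reads was not tested, and an incomplete deletion in that thymus together with a tumour of its own stays open. If the mixture is real, most of the size of the decreases of Sall3, Erc2 and the other genes high in wild type with MNU may follow from it in the knockout, while Pth, Bpifa1 and Chga are not among them.

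Markers of other cell types differed to unequal degrees and in both directions in wild type with MNU, from a median of -6.13 for thymic epithelial genes to 1.40 for neutrophil genes. If the listed genes were transcribed by those cells alone, 1 common dilution factor for every other cell type would give equal medians. The fibroblast and thymic epithelial medians differed by 5.94 on the log2 scale (bootstrap interval over genes 3.95 to 8.51), which argues against it on that condition. The condition was not tested, and 9 of 24 fibroblast genes were at least 2-fold higher and 4 lower. An effect of MNU on the makeup of the wild-type thymus stays open and was not tested, since each group had 1 library.

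Adipocyte genes were lower in knockout with MNU than without. Less fat attached to the dissected thymus and an effect of MNU on fat cannot be told apart: 25 of 27 adipocyte genes were lower, as both would give, and each group had 1 library.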

How the results depend on the processing

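The subtraction of the wild-type MNU share and the replacement of a library were chosen after seeing the data; the other alternatives were set beforehand. No paired analysis was possible because each group had 1 library and no test was run. Under the alternatives set beforehand, 109 of 120 counts of genes or lists lay within 1.5 times the main count, and the 11 others were those with the 4-fold threshold, which by its construction calls fewer genes. With it MNU in wild type gave 259 higher and 686 lower, MNU in knockout 10 and 73, knockout against wild type without MNU 92 and 4, and with MNU 724 and 267. The shared changes then numbered 3, the opposite changes 68 and the differences of the MNU changes 573. Under the same alternatives 549 list medians kept their direction and stood apart and 4 no longer stood apart. For the largest single genes 508 values kept direction and stayed at or beyond the fold threshold in use, and 4 fell below the 4-fold threshold. Camk2g and Myc levels moved little with the scaling, whose factors lay between 0.987 and 1.02 for upper quartiles.

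With the wild-type MNU share subtracted, MNU in knockout gave 198 genes lower, knockout without MNU 182 higher, shared changes 136 and opposite changes 38. The list medians that changed sign were, for MNU in knockout, MYC-activated (0.054), S phase (0.12), G2/M (0.041) and interferon-induced genes (-0.067), and for knockout against wild type without MNU, MYC-activated (-0.027), G2/M (-0.12) and NOTCH target genes (-0.075). Of these, MYC-activated in both comparisons, G2/M for MNU in knockout and NOTCH target genes no longer stood apart. The subtraction also moved the median of all genes, to 0.041 for MNU in knockout and -0.032 for knockout against wild type without MNU. A small change of sign can follow from that shift alone. The medians that kept their sign and no longer stood apart were, for MNU in knockout, NOTCH target (-0.01), mature single-positive (0.097), dendritic (0.016) and plasma cell genes (0.094), for knockout against wild type without MNU, T lymphoma (-0.13) and glycolysis genes (0.025), and for MNU in wild type, whose values the subtraction leaves as they are, alkylation and mismatch repair genes. Single genes changed sign for MNU in knockout (Sall3 0.15, Dpf1 1.16, Erc2 0.94, Iltifb 0.39, Kcnf1 0.39) and for knockout against wild type without MNU (Sall3 -0.37, Erc2 -0.58, Iltifb -0.26, Cym -0.022). All of them were among the 42 genes that set the share, and subtracted levels below 0 were set to 0. Their signs are therefore no separate check on the share. With knockout with MNU set against wild type without MNU, 166 genes were higher and 117 lower, in place of both comparisons that use the knockout library without MNU. The cause of these moves was not tested beyond the share itself. Values of a few units are near the step of 1 read, and differences of such genes depend on the pseudocount.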

Other observations

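Both knockout libraries were set against wild type without MNU, a comparison chosen after the data were examined, in which the knockout library with MNU differs in MNU as well as in genotype. B cell genes had a median log2 difference of 0.82 in knockout without MNU (share subtracted), where 3 of 15 were at least 2-fold higher, and 1.36 in knockout with MNU, where 14 of 15 were, among them Ms4a1 (413 in wild type without MNU and 1248 in knockout with MNU) and Cd22 (451 and 1422). Plasma cell genes stood at 0.94 and 0.80, NK and cytotoxic genes at 1.13 and 0.82, and macrophage genes at 0.65 and 0.84. Double-positive thymocyte genes stood at -0.38 and -0.21. Other lists stood apart in opposite directions in the knockout libraries: thymic epithelial (0.17 and -0.36), fibroblast (0.061 and -0.27), adipocyte (0.10 and -1.15) and histone genes (-0.19 and 0.28). Both comparisons share 1 wild-type library, so an unusual value there would enter both alike.

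Levels of Pth, Chga and Bpifa1 followed neither genotype nor MNU alone over the 4 libraries, and the cells they came from were not tested. Pth stood at 257 in wild type without MNU, was listed at 0 in wild type with MNU, and stood at 2.22 in knockout without and 804 in knockout with MNU. Chga stood at 337, 8.25, 45.8 and 1262 in the same order, and Bpifa1 at 226, listed at 0, 80.8 and 3141.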
